A study of Homo sapiens with 6 samples.

How the data were processed

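Poly(A) RNA of SW620 cells, an established human colorectal cancer line derived from a lymph node metastasis, was sequenced from 3 libraries of cells carrying a lentiviral ELAPOR1 construct and 3 libraries of cells carrying the empty vector. Per the labels' protocols, cells were infected at a multiplicity of 20, selected with 2 ug/ml puromycin and grown with 10% serum, and libraries were made from 1 ug of total RNA after oligo(dT) selection with random priming. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate transductions or cultures, so the p-values measure only the spread between these libraries, which may be technical.

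The deposited table holds read counts per gene, which per the submitters' processing notes came from a workflow naming cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2 and the GRCh38 build. The counts were deposited without normalization and summed to between 16401813 and 20571924 per library. The authors also deposited FPKM values, and all 142222 FPKM values of genes with a count lay within 0.01 of the count over exonic length and library total. The authors' second table gives log2 fold changes and p-values of their own comparison. DESeq2 with a local dispersion trend, run on the deposited counts, called the same 3263 genes as the authors' deposited table, and the largest difference in log2 fold change was 5.59e-09. The libraries were matched to columns by the column names, with K read as the ELAPOR1 construct (older symbol KIAA1324) and NC as the negative control. Whether counting used strand is not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart. Genes with close copies, among them CEACAM5, HLA-B, HLA-F, TUBB2B, AKR1C1, AKR1C2 and histone and ribosomal protein genes, are uncertain where reads match more than 1 copy.

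Counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM factors, quasi-likelihood test of ELAPOR1 against vector, Benjamini-Hochberg adjusted p under 0.05, two-sided). Of 60605 genes in the table, 16003 passed the filter. Standard errors of log2 fold changes were taken as the absolute fold change over the square root of F. CPM values use the TMM factors. Biotypes came from GENCODE 29 by gene identifier, which matched 15825 of the 16003 genes, and from RefSeq by symbol where that gave none. In all, 15838 genes had a biotype, and tested genes without one could not enter the ranking of protein-coding genes. Replicates were compared before averaging: within groups, the mean chi-square per gene of pairs of libraries lay between 2.46 and 3.66, above the value of 1 that sampling noise alone gives, so no pair was treated as 1 library.

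Gene lists and the rule for named genes were fixed before the data were examined. The rule takes ELAPOR1 and ELAPOR2; the 12 highest and 12 lowest log2 fold changes among protein-coding genes past the threshold with a mean of at least 1 CPM and no overlap of the groups; and from each list up to 3 called members with the largest change, or, where none passed, the member with the smallest p by its value. A few further members are named as examples after their values were seen, and some genes that the rule selects are not reported here. The 30 lists cover mesenchymal and EMT genes, epithelial junctions, absorptive and goblet cells, Wnt and stem cell genes, EGFR and MAPK output, TGF-beta, YAP and TAZ, the unfolded protein response, ATF4 targets, lysosome, autophagy, endosome sorting, apoptosis, G1/S, G2/M, p53, type I interferon, NF-kB, MHC class I, cholesterol synthesis, hypoxia and glycolysis, matrix proteases, mitochondrially encoded mRNAs, ribosomal proteins, histones, and fibroblast, immune, endothelial and kidney or neuronal markers. Lists with at least 5 tested members were tested with camera in limma 3.58.1 (inter-gene correlation 0.01), again with an estimated correlation, and with fry.

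The calculations were tested on simulated data. In the simulated ELAPOR1 against vector comparison, 200 genes were changed and 15515 genes were tested. There edgeR recovered 65.7% of changes of 1.25-fold, 91.0% of 1.5-fold and 97.0% of 2-fold, with 8 false calls among 177. The changed genes were drawn from above the 0.25 quantile of vector expression, so recovery at lower levels was not measured. As many rises as falls were planted, and none as large as that of ELAPOR1. Alternatives were DESeq2 1.42.0, RLE factors, library sizes alone, no filter or at least 10 counts in all libraries of a group, a replicate block, limma on log2(FPKM + 1) or log2(FPKM + 0.1) with at least 0.5 FPKM in 3 libraries, stricter thresholds, ELAPOR1 left out, and each library left out in turn.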

Results

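The 6 libraries of SW620 colorectal cancer cells were compared to ask how overexpression of ELAPOR1, an endosome and lysosome associated transmembrane protein, changes gene expression. The 3 vector libraries held 19410332, 20571924 and 16401813 counts in total, and the 3 ELAPOR1 libraries held 16457436, 19268166 and 17984626.

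ELAPOR1 itself (ENSG00000116299, GRCh38 chromosome 1, 109113679 to 109206781, plus strand) rose from 10.4 ± 1.47 CPM in vector cells to 21126 ± 362 CPM in ELAPOR1 cells (SD, n = 3 each). The log2 fold change was 10.97 with a standard error of 0.037 and an adjusted p of 1.31e-105 by edgeR. Its transcripts made up 2.12%, 2.10% and 2.06% of all counts in the ELAPOR1 libraries. Gene counts do not separate the construct from the endogenous gene. Its paralog ELAPOR2 stood at 49.5 ± 2.81 CPM in vector cells and 49.6 ± 2.08 CPM in ELAPOR1 cells, with an adjusted p of 0.999.

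Beyond ELAPOR1, the strongest rise was that of HMCN1, which encodes the extracellular matrix protein hemicentin (chromosome 1, 185734391 to 186190949). It rose from 0.171 ± 0.125 to 52.6 ± 1.77 CPM, a log2 fold change of 8.17 ± 0.178 (SE) that rests on 6, 3 and 1 counts in the vector libraries. MAN2A1, a Golgi mannosidase of N-glycan maturation (chromosome 5, 109689927 to 109869625), rose 8.40-fold from 47.1 ± 0.148 to 395 ± 15.4 CPM. The somatostatin receptor gene SSTR1 rose by 4.17 on the log2 scale, AP1M2, an epithelial clathrin adaptor subunit, by 3.51, and PRODH2 by 3.32. DDC, TMEM30B, CAPN3, GBP2, MGAT4A, an N-glycan branching enzyme, and COL4A1 rose by between 2.49 and 3.23, from below 1 CPM in each case. With few vector counts, single libraries set the size of some of these changes. Without vector replicate 1, the log2 fold changes were 8.84 for HMCN1, 4.92 for SSTR1, 4.16 for AP1M2, 4.40 for PRODH2 and 4.001 for DDC, and without vector replicate 3 that of MGAT4A was 3.41. CAPN3 overlaps ZNF106, DDC overlaps FIGNL1, TMEM30B overlaps PRKCH and COL4A1 overlaps COL4A2, so their reads may not be separable. ZNF106, with 38426 counts in all against 491 for CAPN3, itself rose by 2.19 on the log2 scale, and COL4A2 rose by 0.22, so the values of CAPN3 and COL4A1 are uncertain. FIGNL1 and PRKCH had log2 fold changes of 0.00 and -0.07 with adjusted p of 0.965 and 0.935.

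Among genes that fell, EPN2, an epsin of clathrin-mediated endocytosis (chromosome 17, 19215615 to 19336715), dropped 10.7-fold from 140 ± 6.25 to 13.03 ± 0.472 CPM. CEACAM5, which encodes carcinoembryonic antigen (chromosome 19, 41708585 to 41730433), dropped 8.02-fold from 96.3 ± 2.93 to 11.98 ± 0.581 CPM. The transcription factor gene ONECUT3 changed by -4.47 on the log2 scale, the calcium channel gene CACNA1E by -4.02 and AFF2 by -3.36. CYTL1, VSIG1, PWWP3B, NDRG1, the Rab5 regulator RIN2, the coagulation factor gene F7 and TUBB2B changed by between -2.93 and -2.05. Among the 12 protein-coding genes with the highest and the 12 with the lowest log2 fold changes, the largest adjusted p was 2.01e-06, for MGAT4A.

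**Figure D1:**
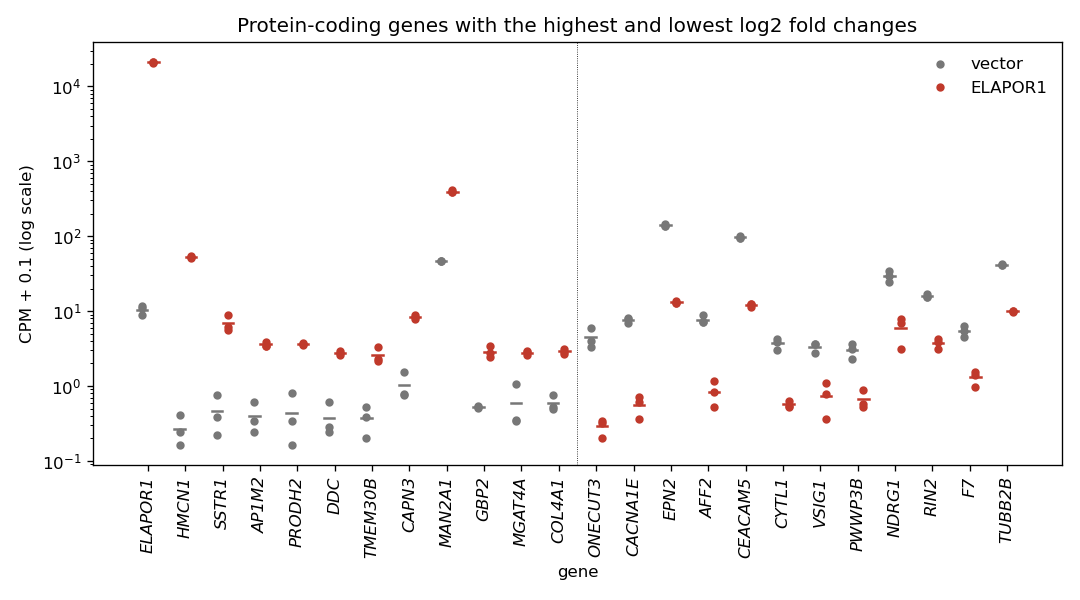
CPM plus 0.1 on a log axis for the 12 protein-coding genes with the highest and the 12 with the lowest log2 fold changes, in order. Points are single libraries (grey vector, red ELAPOR1, 3 each) and bars are group means. Only genes whose groups do not overlap could be chosen. MAN2A1 lies at 395 CPM in ELAPOR1 cells against 47.1 in vector cells.

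Across the transcriptome, 1607 genes were higher and 1820 lower in ELAPOR1 cells, 3427 of 16003 tested. Most changes were small: 2553 of these genes changed by less than 0.5 on the log2 scale, and 361 (240 higher, 121 lower) by at least 1. The groups did not overlap for 33.8% of tested genes, where chance gives 10% for 3 against 3. limma on log2(FPKM + 1) called 727 higher and 1406 lower, a split further toward lower genes. With library sizes alone as scaling, edgeR called 1351 higher and 2183 lower, so the balance of higher and lower genes depends on the scaling. The median log2 fold change of all genes was -0.0169 with limma on log2(FPKM + 1), -0.0174 with library sizes alone and 0.00407 with TMM factors.

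Hypoxia and glycolysis genes fell together. Of 24 tested members 21 fell and none rose (21 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.46 and an adjusted p of 4.87e-21 by camera, against an adjusted p = 0.127 with an estimated correlation. NDRG1 dropped from 29.6 ± 4.85 to 5.89 ± 2.57 CPM, PFKFB4, a regulator of glycolytic flux, from 33.8 ± 3.42 to 13.7 ± 2.52 CPM, and ALDOC from 5.09 ± 0.162 to 2.30 ± 0.691 CPM. The abundant glycolytic genes LDHA and PGK1 changed by -0.41 and -0.51. VEGFA, a hypoxia-induced growth factor gene, had a log2 fold change of 0.09 with an adjusted p of 0.0898.

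Genes of DNA replication and of mitosis moved in opposite directions. In the G1/S list, 10 of 22 members rose and 2 fell (10 and 2 adjusted over the list alone), among them MCM5 and MCM6 of the replicative helicase at 0.30 and 0.28, with an adjusted p of 0.00924 by camera and an adjusted p = 0.419 with an estimated correlation. In the G2/M list, 13 of 23 members fell and none rose (15 lower adjusted over the list alone), among them the mitotic kinase genes AURKB and PLK1 at -0.30 and -0.29 and the kinesin gene CENPE at -0.31, with an adjusted p of 8.49e-06 and an adjusted p = 0.127 with an estimated correlation. Of 10 histone genes tested 3 fell (4 adjusted over the list alone), led by H2AC6 at -0.83, and that list did not pass, with an adjusted p of 0.130.

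Wnt target and intestinal stem cell genes rose: 11 of 22 were higher and 2 lower (11 and 3 adjusted over the list alone), with an adjusted p of 0.000121 and an adjusted p = 0.127 with an estimated correlation. LGR5, a stem cell marker and R-spondin receptor, rose from 60.6 ± 1.78 to 106 ± 8.45 CPM and CD44 by 0.90 on the log2 scale, while TNFRSF19 changed by -0.90. LGR5 overlaps TSPAN8 on the other strand, which rose by 0.47. Of 12 YAP and TAZ targets 4 rose, among them PTPN14 at 1.05 and AMOTL2 at 0.53, and 2 fell, among them CRIM1 at -1.48 (4 and 2 adjusted over the list alone). The adjusted p of that list was 0.00924, was 0.0519 without ELAPOR1 replicate 2, was 0.151 on ranks, an alternative chosen after seeing the data, and was adjusted p = 0.127 with an estimated correlation.

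Of 14 mesenchymal and EMT genes 6 fell and none rose (7 lower adjusted over the list alone), including the fibronectin receptor gene ITGA5 at -0.69 and TGFBI at -0.50, with an adjusted p of 0.000143 and an adjusted p = 0.127 with an estimated correlation. Epithelial junction genes went both ways, with 9 of 22 lower and 2 higher (9 and 2 adjusted over the list alone), an adjusted p of 0.00142 and an adjusted p = 0.241 with an estimated correlation. On ranks that call was lost, at an adjusted p of 0.0516. E-cadherin, CDH1, dropped from 414 ± 11.7 to 244 ± 3.27 CPM, while CDH17 and CLDN7 rose by 1.05 and 0.57. Of 14 absorptive colonocyte genes 4 fell, among them CEACAM5, KRT20 and CDX2, and 1 rose (4 and 2 adjusted over the list alone), with a median of -0.04, an adjusted p of 0.000667 and an adjusted p = 0.127 with an estimated correlation. The absorptive call was lost on ranks, at an adjusted p of 0.769, and on FPKM, at 0.214. Of 6 goblet cell genes GFI1 rose and TFF3 fell (1 and 1 adjusted over the list alone), with an adjusted p of 0.995.

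Chaperones and other genes of the unfolded protein response were lower, with 14 of 21 members down and none up (15 lower and 1 higher adjusted over the list alone), an adjusted p of 0.000265 and an adjusted p = 0.127 with an estimated correlation. DNAJB9 changed by -0.65 and HYOU1 from 250 to 198 CPM. MHC class I genes were higher, with 6 of 14 members up and none down (7 and 1 adjusted over the list alone), an adjusted p of 0.00924 and an adjusted p = 0.127 with an estimated correlation. The median log2 fold change of the list was 0.10. HLA-B rose from 12.5 to 29.5 CPM, HLA-F by 1.63 and the class I transactivator gene NLRC5 by 1.02 on the log2 scale. HLA-F had 9 to 47 counts per library and overlaps HLA-F-AS1 on the other strand. HLA-F-AS1 had 297 counts in all against 174 for HLA-F and a log2 fold change of 0.57, so the value of HLA-F is uncertain. The NLRC5 call was lost with limma on FPKM, at an adjusted p of 0.0841 with a pseudocount of 1 and 0.112 with 0.1.

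**Figure D2:**
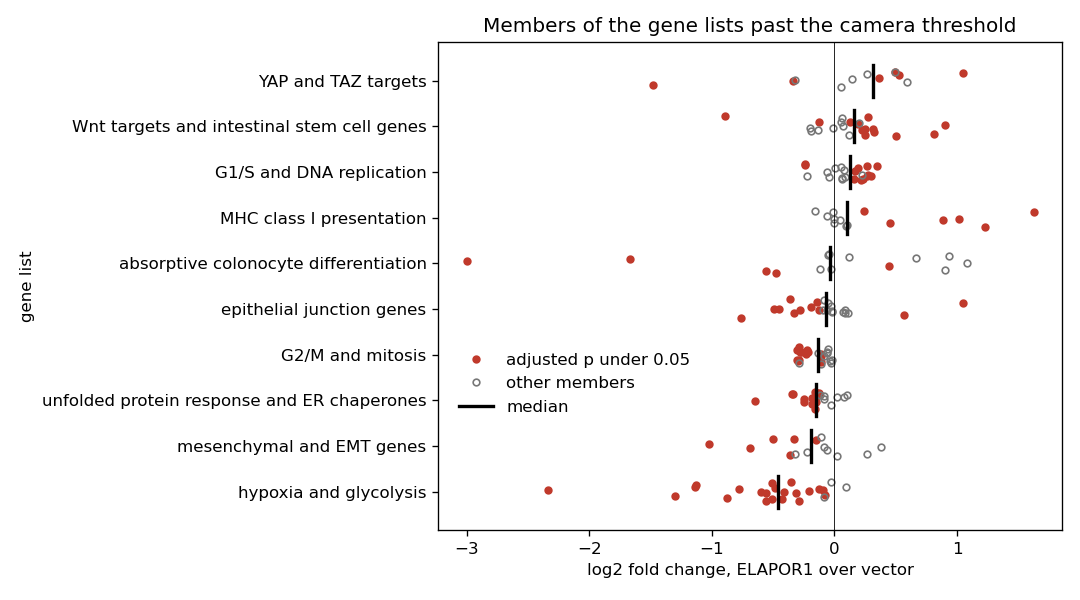
Log2 fold changes, ELAPOR1 over vector, of the members of the 10 gene lists past the camera threshold. Filled red points are genes at an adjusted p under 0.05, open grey points are other members and black bars are list medians; the hypoxia and glycolysis list has the lowest median, at -0.46.

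The other lists did not pass camera. Higher and lower members, with counts adjusted over the list alone in brackets, were 5 and 4 (6 and 4) of 23 for EGFR and MAPK output, with EGFR at -1.11; 4 and 4 (4 and 4) of 14 for TGF-beta targets, with PMEPA1 at -0.60; and 8 and 4 (8 and 4) of 27 for ATF4 targets, with DDIT4 at -0.69. They were 4 and 4 (7 and 5) of 28 for lysosome genes, with CTSB at -0.25, 7 and 5 (7 and 5) of 30 for autophagy genes, with SQSTM1 at 0.31, and 2 and 2 (2 and 2) of 26 for endosome sorting genes, with LRP1 at -0.67, a call lost with limma on FPKM at adjusted p of 0.112 and 0.124 with pseudocounts of 1 and 0.1. Apoptosis genes gave 5 and 6 (5 and 7) of 30, with PMAIP1 at 0.62, and p53 targets 3 and 3 (3 and 3) of 22, with BTG2 at -0.79. Type I interferon genes gave 3 and 1 (3 and 1) of 20, with OAS2 at 1.08, NF-kB targets 5 and 4 (5 and 4) of 16, with TNFAIP2 at -0.98, and cholesterol synthesis 7 and 4 (8 and 4) of 25. Matrix proteases gave 4 and 4 (4 and 4) of 11, with MMP7 at 1.57, mitochondrially encoded mRNAs 5 and 0 (7 and 1) of 13, a list that passed on ranks at an adjusted p of 0.0167, and ribosomal proteins 9 and 2 (10 and 3) of 40. Among markers of other cell types, 2 of 5 fibroblast genes rose (2 adjusted over the list alone), with LUM from 14.9 to 23.4 CPM and ACTA2 from 0.217 to 0.812 CPM, and 0 of 5 immune, 0 of 2 endothelial and 0 of 2 kidney or neuronal genes passed (0 adjusted over the list alone in each). ACTA2 had 3 to 18 counts per library and overlaps FAS, which rose by 1.07 and had 229 counts in all, and STAMBPL1, which fell by 0.26 and had 2834. The adjusted p of ACTA2 was 0.0766 without vector replicate 1, 0.0721 without vector replicate 2, 0.0533 without ELAPOR1 replicate 1, 0.103 without ELAPOR1 replicate 3 and 0.0501 with no filter. LYZ and VWF had log2 fold changes of 0.18 and -0.21.

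In all, 10 of 28 tested lists passed camera and 0 with an estimated correlation, where 8 had an unadjusted p under 0.05, and fry, which does not compare a list with other genes, called 19. Median, mean and test differed in sign for the goblet, EGFR, lysosome, apoptosis, p53, NF-kB and matrix protease lists, none of which passed.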

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

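The count of 3427 genes was within 1.5 times under DESeq2 (2364), RLE factors, library sizes alone, both filters and ELAPOR1 left out. It was 2133 with limma on log2(FPKM + 1), 2098 with log2(FPKM + 0.1), 2245 at an adjusted p under 0.01 and 361 with a log2 fold change of at least 1; stricter thresholds give fewer genes by construction, and for FPKM the cause was not tested. Chosen after seeing the data, DESeq2 with a local dispersion trend gave 3263 and genes of at least 5 CPM gave 3195, so DESeq2's count depends on its dispersion trend. Leaving out 1 library gave 2723 to 3187 genes, a log2 fold change of ELAPOR1 of 10.87 to 11.04, and 9 to 10 lists. The count of 10 lists became 0 with an estimated correlation and 8 on ranks, where 7 of the 10 lists were kept, the epithelial, absorptive and YAP lists were lost and the mitochondrially encoded mRNAs were gained, at an adjusted p of 0.0167. With the replicate block, 3361 genes and 10 lists passed. Deviations of libraries with the same number correlated at 0.02, 0.03 and 0.03, too weakly to treat the numbers as a pairing. All 6 of 6 libraries correlated best with their own number, but each correlation was counted for both of its libraries. These are therefore not 6 independent agreements, and are at most a hint from the data and not the design. Of 98 named genes past the threshold, 82 kept their call under all alternatives that gave a value and 16 lost it under at least 1, none changing direction. Of these, 11 were lost when 1 library was left out, among them EPHA4, SDF2L1, NUPR1, SGSH, TP53INP1, ATG7, HGS, ICAM1 and ACTA2. LRP1, E2F1, NLRC5, TIMP3 and RPL13 lost theirs only with limma on FPKM, with adjusted p between 0.0536 and 0.124. Depth limits genes below 1 CPM, where vector counts were as low as 1.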

Other observations

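The tests on pathways, Gene Ontology terms, neighbouring genes, transduced populations, transgene counts, dishes and genes matched on GC content and length, and the background share of common words, were chosen after results were seen. Among 324 pathways annotated in the deposited table, 3 passed camera and 0 with an estimated correlation, where the smallest adjusted p was 0.767; among 1918 Gene Ontology terms 25 passed and 0 with an estimated correlation. Steroid hormone biosynthesis was higher, with 7 of 27 genes up and 2 down and an adjusted p of 0.0328. The aldo-keto reductase genes AKR1C1 and AKR1C3 rose from 19.6 ± 2.22 to 53.9 ± 1.68 CPM and from 96.1 ± 7.37 to 179 ± 4.03 CPM (SD, n = 3). HSD17B2, CYP1B1 and CYP1A1 rose by 1.72, 1.70 and 1.48 on the log2 scale, but from low levels. Their means went from 1.02 to 3.35, from 0.743 to 2.45 and from 0.997 to 2.79 CPM. Protein export genes were lower, with 13 of 26 down and none up and an adjusted p of 0.00565, led by the translocon genes SEC61G at -0.43 and SEC61A1 at -0.36. The third pathway, named for African trypanosomiasis, had 5 of 13 genes up, with F2RL1, a protease-activated receptor gene, at 1.62.

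For the count of 3427 genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest other gave 0. For the 10 lists it was also 1 of 10, and the highest other gave 6. With 10 splits a share under 0.05 cannot be reached. Every other split also mixes ELAPOR1 and vector libraries, so the group difference enters the spread within its groups and can lower its counts.

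Besides ELAPOR1, 38 genes with a mean of at least 1 CPM changed by 2 or more on the log2 scale, 24 up and 14 down. A copy-number change of the surrounding 500 kb is argued against for the 36 of them with an expressed neighbour. The median shift of neighbours was 0.02441 (quartiles -0.0257 and 0.0626), where positive values go the same way as the nearby gene. SSTR1 and GLI3 had no such neighbour and were not covered, and AFF2 and CD8B2 had only 1 each. The largest neighbour median of a single gene was 0.332, for CYTL1, which itself fell, so its neighbours fell with it. Neighbours that were themselves among the 38 were left out, so pairs such as CAPN3 and the overlapping ZNF106 were not seen. The largest running median over 31 genes, 0.159, lay under the 0.160 reached at the 95th percentile of permuted orders. A change within 1 gene, or within adjacent genes that are all among the 38, was not tested. For reads of the transgene, 16.67% of the genes that rose share a 25-base word with ELAPOR1 transcripts, between the bounds set beforehand. The share was 39.0% among 500 unrelated genes. The 20 of 24 that share none include HMCN1 and MAN2A1, which argues against misassigned ELAPOR1 reads for these 20. For the 4 that share a word this stays open: MGAT4A with 36 words, ZNF106 with 18, and CRAT37 and GAB1 with 2 each. A difference between the transduced populations, such as vector insertion or outgrowth of a clone, may equally give such genes. For 100% of them the groups did not overlap, but genes picked for a large change past the threshold would mostly show this anyway. A response to ELAPOR1 gives it too, so a population difference and a response cannot be told apart.

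Removing a trend on GC content and length left the median of the hypoxia and glycolysis genes at -0.4564, against -0.4586 before, but moved no member by more than 0.0207 and so decides nothing. The 100 genes nearest to each member in GC content and length had a median of 0.01403 (quartiles -0.00395 and 0.0218). That argues against a bias shared by genes of like GC content and length as the source of the fall. It reflects the same small trend, and so is not independent of the trend removal. Counts taken up by the transgene would lower all genes alike, but ELAPOR1 made up only 2.06% to 2.12% of counts in the ELAPOR1 libraries. That is too little to lower other genes as far as the list fell. The median of all tested genes with library sizes alone, -0.01743, was therefore bound to be small and adds no further evidence. Oxygen or density of the dishes at harvest may be the source: the SD within groups was 0.1377 of the difference between groups, and dishes of 1 group handled alike would give this too, so it cannot be told apart from a response to ELAPOR1.

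For the opposite movement of replication and mitosis genes, removing the GC and length trend also moved too little to decide, with a difference of list medians of 0.2583 before and 0.2571 after. The genes matched to the 2 lists differed in their medians by -0.000864, which argues against a bias shared by genes of like GC content and length. Here too the matched genes reflect the same small trend and are not independent of its removal. Changes in the share of cycling cells or in cycle phases were not tested, and neither list passed with an estimated correlation.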
